A study of Saccharomyces cerevisiae with 3 samples.

How the data were processed

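Total RNA of Saccharomyces cerevisiae was measured on 3 two-colour arrays, numbered replicates 1 to 3 in the labels. On each array RNA of a strain labelled YAP1 mutant was set directly against RNA of the wild type, both after 1 h in 1.0 mM arsenite, the trivalent form of arsenic. Per the labels, the mutant RNA carried Cy5 and the wild-type RNA Cy3 on all 3 arrays, so the dye and the genotype cannot be told apart. The labels do not say that the replicates were separate cultures, and the p-values then measure only the spread between these arrays, which may be technical.

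The deposited values are log2 ratios, 1 per spot, for 13056 spots per array with no missing value. Raising 2 to a value gave a ratio of whole numbers for 100% of the spots within a relative tolerance of 1e-13, whereas bases e and 10 did so for at most 0.20%. Scanner, image software, background handling and any normalization by the authors are not given in the sources used here. The values were neither centred nor normalized: the medians of the 3 arrays were -0.52, -0.85 and -0.55. The table does not state the direction of the ratio. Mutant over wild type is called likely here, from the order of the sample titles, the dye labels and the lower YAP1 signal on all 3 arrays, and every direction below rests on it.

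Both channel signals were recovered from the whole-number ratios up to a common factor, which was settled with the duplicate spots; on simulated signals the recovered mean log2 signal lay within 0.5 of the true one for 83.4%, 85.2% and 91.2% of spots. The median deposited ratio was -1.11, -1.19 and -1.32 on the 3 arrays in the brightest 10% of spots, and -0.17, -0.69 and -0.35 in the dimmest 10%. The plan made before the data were examined kept the deposited scale unless the table was not normalized. Because it was not, a loess curve of the ratio on the recovered signal (span 0.3, limma 3.58.1 in R 4.3.3) was subtracted within each array, a choice made after seeing the data. The deposited scale, loess with print-block medians and normexp before loess were added as alternatives after seeing the data. Print blocks, duplicate spots and print neighbours were inferred from the order of the values, since no print layout was used.

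Gene names came from the platform annotation table: 11138 spots had 1 gene, 1918 none and 0 several. These spots stood for 5539 genes, of which 5510 had 2 spots, and 5534 were matched in a RefSeq gene table of the R64 assembly, used only for names and for the order of genes along the chromosomes. The coordinates of the array's probes were not used here. Spots of a gene were averaged within an array. Genes were tested with limma's moderated test of the mean log2 ratio against 0, two-sided, and called changed at a Benjamini-Hochberg adjusted p under 0.05 over 5539 genes. limma's camera with a preset correlation of 0.01 was run on 25 gene lists fixed before the data were examined, those with 3 or more measured genes, and adjusted over the 25. Beside each list stands the number of its members called over all genes and the number called when p was adjusted over the list alone.

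The genes named in the report were fixed by rule before the data were examined: YAP1, the 10 largest decreases and the 10 largest increases among called genes of 1 sign on all 3 arrays, 11 genes of redox, transport and sulfur metabolism, and up to 4 members of smallest p from each list with a called shift or a called member. Other genes named below were chosen after their values were seen. With simulated arrays of the same trend and spread and 5539 genes, limma recovered 20% of 50 genes changed 1.5-fold, 90% of 50 changed 2-fold and 100% of those changed 4-fold or 8-fold, and 3 of 158 calls were false. On the same arrays 0 of 25 random lists were called by camera. The simulated genes varied independently, and no dye effect of single genes was simulated. The simulation therefore does not test camera on lists of correlated genes, nor calls that such a dye effect would give. The number of arrays limits the precision. Alternatives chosen before the data were examined covered centring, scaling, quantile normalization, the median of spots, each array left out in turn, the variance model, thresholds, a spot-level model, a signal filter and other list tests. Figures were drawn with matplotlib 3.10.9, and the values were prepared with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.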

Results

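Gene expression of a strain labelled YAP1 mutant, called a yap1 deletion mutant in the series title, was compared with that of the wild type of Saccharomyces cerevisiae, both exposed to 1.0 mM arsenite for 1 h. YAP1 encodes a bZIP transcription factor of the oxidative stress response. Each of 3 two-colour arrays compared mutant and wild-type RNA directly, and the design asks which transcripts depend on YAP1 in cells under arsenite. Ratios are given as log2 of the likely direction, mutant over wild type, with the standard error of limma's fit and n = 3 arrays throughout.

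In the mutant 19 of 26 genes of the oxidoreductase and detoxification list and 12 of 26 genes of the thioredoxin, glutathione and peroxidase list fell. The drug exporter genes FLR1 and ATR1 fell too. The shifts of both lists passed with camera's preset correlation but not with an estimated one (adjusted p = 0.544 for each), and no list passed with limma's rotation test fry. With 3 arrays the test with an estimated correlation has few degrees of freedom, so it could hardly call a list. For the glycolysis and fermentation list it estimated a correlation of -0.0085, below the preset 0.01. There camera's unadjusted p still rose from 2.59e-04 to 0.0524. Of the other lists with a camera shift, the ribosomal protein list also had an estimate below the preset (9.0e-05). Estimates exceeded the preset for the oxidoreductase (0.627), proteasome (0.493) and alpha mating type (0.937) lists. They also did for the thioredoxin (0.196), ribosome biogenesis (0.101) and arsenic handling (0.103) lists. For these, camera's p-values at the preset correlation may be too small. How much of each loss came from correlation and how much from the few degrees of freedom was not tested. The largest decrease was that of OYE3, an NADPH dehydrogenase gene, at -4.32 ± 0.15 (limma, adjusted p = 7.69e-08). FLR1 (-3.56 ± 0.17) and the methylglyoxal reductase gene GRE2 (-3.16 ± 0.14) fell, both with adjusted p = 5.33e-07. Of 5539 genes, 166 fell and 25 rose, and 77 of the former and 9 of the latter changed by 2-fold or more. All 191 had 1 sign on all 3 arrays.

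YAP1 was examined first. It had ratios of -0.33, -1.22 and -1.07 on the 3 arrays and a mean of -0.87 ± 0.18 (limma, adjusted p = 0.0253). The mean no longer passed without replicate 2 (-0.70), with arrays scaled to 1 spread (-1.10), with normexp before loess (-1.36), with spots as technical replicates (adjusted p = 0.198), with the unmoderated statistic (adjusted p = 0.510) or at an adjusted p under 0.01. Among the alternatives under which the mean passed were median centring (-1.30), block medians (-1.03), leaving out replicate 1 (-1.14) and the uncentred deposited scale (-1.94). The recovered YAP1 signal had a mean log2 of 11.1 over both channels. This mean includes the wild-type channel. The deposited ratios of -1.26, -2.34 and -2.23 then place the mutant channel, averaged over the arrays, above that of the median spot. The median spots of that channel had signals of 610.5, 910 and 737. Background handling is not given, so neither this signal nor the ratios show whether the transcript is missing. The part of the gene that its spots cover was not used here, so whether it lies in a deleted part is open.

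The other decreases among the 10 largest were those of YNL134C (-4.11), YML131W (-3.25), OSI1 (-3.13), AAD3 (-2.90), AAD6 (-2.80), YLL066C (-2.72) and the glyoxalase gene HSP31 (-2.68). Mean log2 signals were 11.7 for OYE3, 11.1 for FLR1 and YLL066C and 10.9 for OSI1. Their deposited ratios then place the mutant channel near its 5th percentiles of 348, 628 and 548 on the 3 arrays. GRE2, with a mean log2 signal of 13.6, lay well above these. Whether the signal floor limited the size and order of the largest decreases was not tested. The aryl-alcohol dehydrogenase genes AAD3 and AAD6 belong to a family of near-identical sequences, and their spots may have read each other's transcripts. The increases were smaller. The largest were those of VAS1, the valyl-tRNA synthetase gene (1.45 ± 0.14, adjusted p = 1.11e-04 by limma), PDC6, a pyruvate decarboxylase gene (1.36), MCH5, a riboflavin transporter gene (1.30), and ASC1, which encodes a ribosome-bound protein (1.28). YBL005W-A (1.12), YML040W (1.09) and YML045W (1.00), which are transposon reading frames, and FBA1 (1.05), RSC30 (1.03) and PDC1 (0.95) completed the 10. The mean log2 signal was 14.8 for YBL005W-A, 15.2 for YML040W, 15.7 for YML045W, 14.9 for FBA1 and 15.8 for PDC1, against 9.6 for RSC30. Apart from RSC30, these genes had negative deposited ratios on all 3 arrays, so their increases rest on the normalization. Whether the ratios of spots this bright are compressed was not tested. Size and order depended on the loess step: with median centring VAS1 had 0.86, PDC6 0.77, MCH5 1.12, ASC1 0.80 and RSC30 1.13. ASC1 had 0.25 on replicate 1 against 1.58 and 2.01 on replicates 2 and 3.

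**Figure D1:**
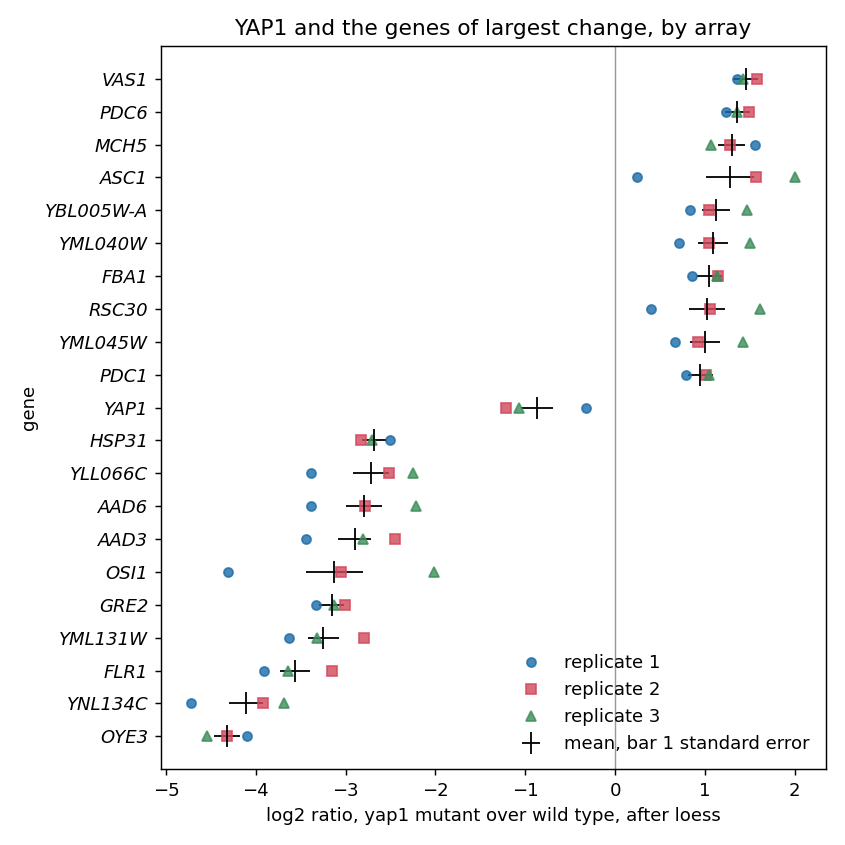
Log2 ratio of mutant over wild type after loess (horizontal axis) for YAP1 and the 10 largest decreases and 10 largest increases (vertical axis); symbols are the 3 arrays, black ticks the means and bars 1 standard error. OYE3 lies lowest, at a mean of -4.32, VAS1 highest, at 1.45, and the 3 arrays of ASC1 lie between 0.25 and 2.01.

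In the oxidoreductase and detoxification list, not all of whose genes need be oxidoreductases, 19 of 26 measured genes fell and 0 rose (20 fell when adjusted over the list alone). Beyond OYE3, GRE2 and YNL134C they included OYE2 (-2.46), AAD4 (-2.47), AAD14 (-2.68), AAD15 (-2.61), AAD10 (-2.17) and FRM2 (-1.55). AAD3, AAD4, AAD6, AAD10, AAD14 and AAD15 are of the same family, whose spots may read each other's transcripts, so their decreases need not be separate. The list was not run with this family reduced. The list had a median of -1.91 and shifted lower (camera, adjusted p = 5.29e-29, and adjusted p = 0.544 with an estimated correlation).

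Of 26 thioredoxin, glutathione and peroxidase genes 12 fell and 0 rose (14 fell when adjusted over the list alone). The superoxide dismutase gene SOD1 (-2.37), the thioredoxin gene TRX2 (-2.35), the thioredoxin reductase gene TRR1 (-2.30) and the glutathione reductase gene GLR1 (-2.01) had the largest decreases in the list. GPX2 (-1.46), GRX2 (-1.42), SOD2 (-1.30), TSA1 (-1.29), PRX1 (-1.27) and TSA2 (-1.15) also fell. The list's median was -0.44, with camera's adjusted p = 1.90e-11 and an adjusted p = 0.544 with an estimated correlation.

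Both genes of glutathione synthesis fell, GSH1 with -1.19 ± 0.16 (limma, adjusted p = 0.00153) and GSH2 with -1.64 ± 0.19 (adjusted p = 4.34e-04). In the list of glutathione and cysteine synthesis ECM38 also fell (-0.90), DUG2 (0.81) and DUG3 (0.63) rose, and 6 of 11 did not pass. With median centring DUG2 (0.18) and DUG3 (0.17) did not pass. Adjusted over the list alone, 5 fell and 2 rose, and the list as a whole did not pass (camera, adjusted p = 0.0596). CYS3 had -0.36 and did not pass, but it did with median centring (-0.91).

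The arsenic handling list held GSH1 and GSH2 as its 2 lower genes of 10 (3 when adjusted over the list alone), shared with the lists above. ARR3, the arsenite exporter gene, had -1.49, 0.00 and -0.97 on the 3 arrays, a mean of -0.82 ± 0.23 that did not pass (limma, adjusted p = 0.0936). The vacuolar transporter gene YCF1 (-0.32), ARR2 (-0.47) and ARR1 (0.22) did not pass. The list shifted lower with camera's adjusted p = 0.0234, and adjusted p = 0.718 with an estimated correlation. Leaving out every gene that also stands in another list removed YCF1, PHO84 (0.42) and ARR1 as well as GSH1 and GSH2. The list's mean was then -0.38 against -0.44 for the full list, and it no longer passed (camera, adjusted p = 0.0732). The list was not run without GSH1 and GSH2 alone. It also did not pass on the deposited scale, with block medians (-0.36) or with rank camera (adjusted p = 0.0761).

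Of 24 multidrug transport genes FLR1 and ATR1 (-1.80) fell and TPO2 rose (0.66), BPT1 had 0.48 without passing, and the counts were the same when adjusted over the list alone. With median centring TPO2 (0.42) did not pass. The list did not shift (camera, adjusted p = 0.729). In the sulfate assimilation and methionine list 1 of 38 genes fell, the S-methylmethionine permease gene MMP1 (-1.94), against 3 when adjusted over the list alone. MET3 (-0.19), MET16 (-0.17), CYS4 (-0.65), MET5 (-0.56) and BDS1 (-0.61) did not pass. With median centring all of these passed, at -0.80, -0.77, -1.09, -0.91 and -0.90. The list had a median of 0.02, a mean of -0.08 and camera's adjusted p = 0.837. With median centring the list's mean was -0.39 and passed as lower (camera, adjusted p = 0.00108). That mean stood at percentile 65.4 of random lists of equal recovered signal.

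Of 33 glycolysis and fermentation genes 7 rose and 2 fell, and adjusted over the list alone 8 rose and 2 fell. FBA1, PDC1, PDC6, CDC19 (0.91), TDH1 (0.76), TDH2 (0.66) and TDH3 (0.65) rose, and the aldehyde dehydrogenase genes ALD4 (-1.93) and ALD6 (-1.30) fell. TDH2 and TDH3 are near-identical, and their spots may have read each other's transcripts. The list shifted higher (median 0.23, mean 0.17, camera, adjusted p = 0.00129, and adjusted p = 0.544 with an estimated correlation), but with median centring in place of loess its mean turned to -0.19 and did not pass. Of the 7 higher genes only FBA1 (0.43) and PDC6 then passed, and PDC1 (0.33), CDC19 (0.30), TDH1 (0.14), TDH2 (0.04) and TDH3 (0.02) did not. In the pentose phosphate list GND1 (-0.73) and TKL2 (-0.76) fell among 13, SOL4 (0.39) and RKI1 (0.51) did not pass, and the list had a median of -0.02 with camera's direction upward (adjusted p = 0.996). Adjusted over the list alone, 2 of its genes fell and 1 rose.

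The proteasome list shifted lower, with a median of -0.26 and 22 of 36 genes lower on all 3 arrays (camera, adjusted p = 1.93e-04, and adjusted p = 0.783 with an estimated correlation). Lists of genes of equal recovered signal shifted as much: the proteasome mean stood at percentile 47.35 of 10000 such random lists after loess and 44.96 after median centring, whereas the other lists with a camera shift lay outside the central 95% of theirs. RPN4, which encodes the transcription factor of proteasome genes, fell (-0.85), as did RPN2 (-0.63) and RPT2 (-0.62), 6 fell when adjusted over the list alone, and RPN9 had -0.52 without passing. Of 28 heat shock and chaperone genes HSP30 (-1.13), SSA4 (-0.67) and SSC1 (-0.65) fell and SSA3 (-0.53) did not pass, and adjusted over the list alone 10 fell and 2 rose. That list did not shift (adjusted p = 0.0596), but did with median centring, where its mean was -0.71, at percentile 23.08 of random lists of equal signal. Of 44 general stress genes ALD3 (-1.76) and YGP1 (-1.24) fell, GRE1 rose (0.93) and SPI1 had 0.63 without passing (camera, adjusted p = 0.278). With median centring GRE1 (0.37) did not pass, and the list's mean turned to -0.34 and passed as lower (adjusted p = 0.00518), at percentile 98.07 of random lists of equal signal. Adjusted over the list alone, 2 fell and 2 rose.

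Ribosome biogenesis genes shifted higher with a median of 0.21 over 73 genes (camera, adjusted p = 2.56e-06, and adjusted p = 0.717 with an estimated correlation). UTP22 rose (0.72), DBP2 fell (-0.78), and UTP4 (0.58) and CBF5 (0.49) did not pass; adjusted over the list alone, 1 fell and 0 rose. Of 132 cytosolic ribosomal protein genes RPL10 fell by 2.58 and the other 131 did not pass, among them RPL19A (0.56), RPL37A (0.57) and RPL30 (-0.54), with the same count when adjusted over the list alone. The list's small shift upward (mean 0.04, camera, adjusted p = 0.0491, and adjusted p = 0.544 with an estimated correlation) no longer passed when any 1 array was left out (means of 0.02 to 0.06), with scaling, with quantile normalization or with block medians.

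In the metallothionein and copper list SOD1 and its copper chaperone gene CCS1 (-1.39) fell, whereas CUP1-1 (0.80) and CUP1-2 (0.80), identical metallothionein genes whose spots cannot be told apart, rose, and the counts were the same when adjusted over the list alone (camera, adjusted p = 0.660). With median centring the ratios of CUP1-1 (0.17) and CUP1-2 (0.16) did not pass. Amino acid synthesis genes had 4 decreases among 59, ASN1 (-1.03), LYS21 (-0.84), ARG1 (-0.73) and HIS5 (-0.71), against 8 decreases and 1 increase when adjusted over the list alone (camera, adjusted p = 0.0620). That list passed as lower with block medians (mean -0.16) and with median centring (-0.31, at percentile 22.67 of random lists of equal signal). ATP1 fell by 0.84 among 49 genes of respiration, where RIP1 (-0.47), ATP15 (0.45) and HAP4 (0.48) did not pass (adjusted p = 0.278), and 1 gene fell when adjusted over the list alone. RNR2 fell by 0.72 among 28 genes of S phase and histones, against 2 genes when adjusted over the list alone, and HHF1 (-0.57), CLB6 (-0.39) and PCL2 (0.39) did not pass (adjusted p = 0.660). Of the 8 YAP family genes YAP1 alone fell, YAP7 (-0.52) and YAP5 (-0.30) did not pass, with the same count when adjusted over the list alone, and the list did not shift (adjusted p = 0.527).

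The alpha mating type markers had a median of 0.27 over 5 genes, with 0 called over all genes or over the list alone (camera, adjusted p = 0.0451, and adjusted p = 0.783 with an estimated correlation). STE3 (0.31), AFB1 (0.35), MF(ALPHA)1 (0.26) and MF(ALPHA)2 (0.27) did not pass, and the list, with a mean of 0.29, no longer passed without replicate 1 (0.07) or replicate 2 (0.38), with median centring (0.30), scaling, quantile normalization, block medians or normexp. No gene of the a mating type, phosphate, iron, ergosterol, auxotrophic marker or sporulation lists was called, and none of these lists shifted (camera, adjusted p = 0.169, 0.271, 0.729, 0.996, 0.328 and 0.695). Adjusted over the list alone, 1 sporulation gene fell and 1 rose, and none of the other 5 lists had a call. The iron list had a mean of -0.00 and the ergosterol list one of -0.03, with camera's direction upward in both.

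**Figure D2:**
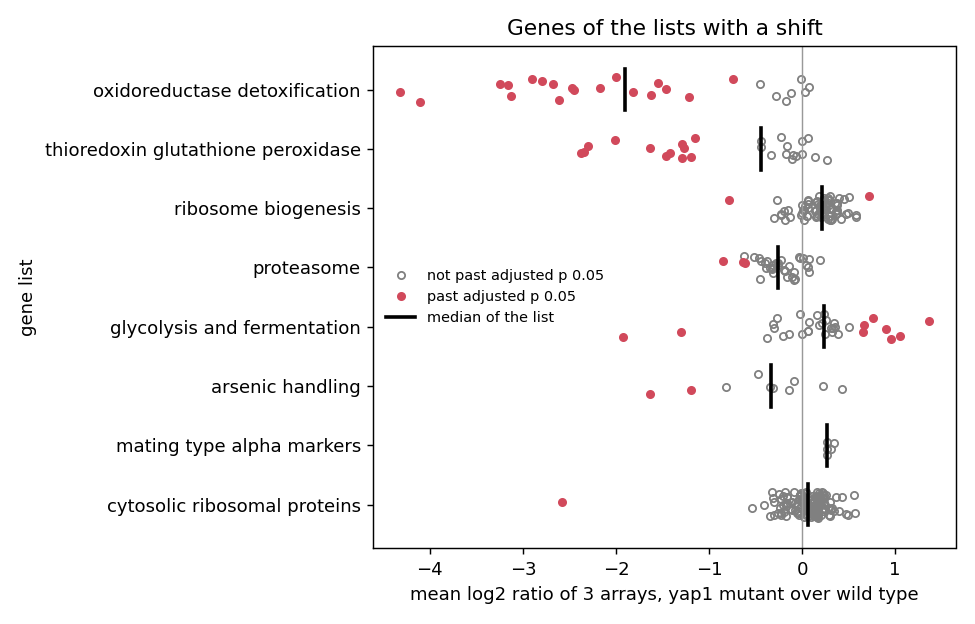
Mean log2 ratio of 3 arrays (horizontal axis) for each gene of the 8 lists with a camera shift (vertical axis); filled points passed limma's test at an adjusted p of 0.05, open points did not, and black lines are list medians. The medians run from -1.91 for the oxidoreductase and detoxification list to 0.27 for the alpha mating type markers. RPL10 lies apart from the other ribosomal protein genes at -2.58.

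The arrays correlated across genes with r = 0.526 (replicates 1 and 2), 0.536 (1 and 3) and 0.669 (2 and 3); genes are not independent replicates. The counts depended on the scaling and on replicate 1. Quantile normalization gave 281 lower and 97 higher genes, median centring 984 and 237, the deposited scale 4191 and 1, and leaving out replicate 1 gave 312 and 84. All 166 lower genes were also called with median centring, but 9 of the 25 higher ones were, and 129 and 5 of them were called with normexp before loess. The 10 largest decreases passed in both, whereas PDC1 and YML045W passed in neither and FBA1, YML040W, YBL005W-A and ASC1 did not pass with normexp. Median centring leaves the lower ratio of bright spots in place, which favours lower calls over higher ones there. The difference between lower and higher genes under it may come from that trend.

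**Figure D3:**
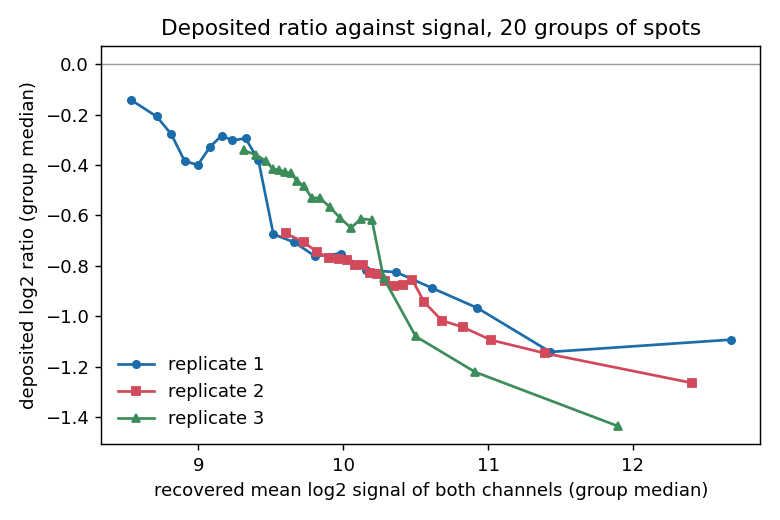
Median deposited log2 ratio (vertical axis) against the median recovered log2 signal (horizontal axis) of 20 equal groups of spots, with a line for each of the 3 arrays. On each array the ratio is lower in the brightest group than in the dimmest, the trend that loess removed.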

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

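Features with no gene name entered none of the comparisons, and 27 of the 959 were lower and 9 higher in the mutant by limma at an adjusted p under 0.05, which is a signal in data outside the gene tests. The lowest of them had a log2 ratio of -2.82. Of the 36, 3 stood next to a called gene in the inferred print order, and 1 of these 3, at -2.67, lay beside OSI1.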

How the results depend on the processing

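The deposited scale, loess with block medians and normexp before loess were chosen after seeing the data. Changed genes numbered 166 lower and 25 higher, changed lists 4 lower and 4 higher, and r averaged 0.577 over array pairs. Median centring gave 984 and 237 genes, 9 and 2 lists and r of 0.722; its spread was pooled fully over genes. The deposited scale gave 4191 and 1 genes, 9 lower lists and r of 0.722, with the median of all genes at -0.66. Scaling gave 40 higher genes and 2 higher lists, and quantile normalization 281 and 97 genes and 2 higher lists. Block medians gave 2 higher lists and r of 0.658, and normexp 2 and 0.482. Leaving out each array in turn gave 140 to 312 lower and 23 to 84 higher genes, 2 to 3 higher lists and r of 0.526 to 0.669. Adjusted p under 0.10 gave 258 and 68 genes, under 0.01 75 and 11, and spots as technical replicates 45 higher. The unmoderated one-sample statistic called 0 lower and 0 higher genes (562 at an unadjusted p under 0.05, against 1093 with limma). camera with an estimated correlation called 0 lower and 0 higher lists (0 at an unadjusted p under 0.05), and fry 0 and 0 (7 unadjusted). Of the 58 named genes that passed, 11 reversed on the deposited scale and 0 under any other alternative, and all 58 passed with quantile normalization, the median of spots and without replicate 1. Those that no longer passed numbered 7 with median centring, 21 with normexp, 9 with block medians and 13 without replicate 3. The glycolysis list also no longer passed with normexp. Of the named genes and the lists that had not passed, 24 passed in the same direction with median centring. Among them were ARR3 (-0.82), CYS3 (-0.91), MET3 (-0.80), MET16 (-0.77) and the heat shock, sulfate, glutathione synthesis and amino acid lists.

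A list counts as reversed where its test's direction against the other genes turned, and the means given for lists need not change sign. Under median centring the direction turned for lists with means of -0.10 (ergosterol), -0.34 (general stress), -0.19 (glycolysis), -0.21 (pentose phosphate) and -0.13 (S phase). On the deposited scale, which is not centred, the direction of these lists also turned, with means of -0.74, -0.98, -0.83, -0.85 and -0.77. Genes reversed there were CUP1-1 (-0.47), CUP1-2 (-0.48), DUG2 (-0.46), GRE1 (-0.27), PDC1 (-0.31), FBA1 (-0.21), YML045W (-0.26), YML040W (-0.17), YBL005W-A (-0.10), TPO2 (-0.22) and UTP22 (-0.085) among those that passed, and ARR1 (-0.44), MF(ALPHA)1 (-0.23), MF(ALPHA)2 (-0.49), STE3 (-0.22), AFB1 (-0.32), SOL4 (-0.60), PCL2 (-0.21), ATP15 (-0.45), BPT1 (-0.26), HAP4 (-0.054), CBF5 (-0.060), RKI1 (-0.054), RPL19A (-0.17), RPL37A (-0.22), UTP4 (-0.23) and SPI1 (-0.62) among the others. The direction of the ergosterol list, whose mean was -0.028, also turned with scaling (-0.027), quantile normalization (-0.031), block medians (-0.018), fry and rank camera (both -0.028) and without shared genes (-0.033). That of the pentose phosphate list, whose mean was -0.049, turned with block medians (-0.088), normexp (-0.17), fry (-0.049), without shared genes (-0.11) and without replicates 1 (-0.086) and 2 (-0.077), but not without replicate 3 (0.017). The direction turned for the copper list (mean -0.23) with block medians (-0.14) and without shared genes (0.0045), for the glutathione synthesis list (-0.34) without shared genes (0.049), and for the sulfate list (-0.080) without shared genes (-0.046) and without replicate 1 (-0.045). The ratios of YAP5 (0.0064) and MF(ALPHA)2 (-0.065, up to 0.50 without another array) and the direction of the iron list (-0.034, up to 0.014) turned without replicate 1, as did those of the iron (-0.0044) and S phase (0.011) lists with fry, whose direction is its own test's. Apart from what the deposited scale's missing centring shows, the cause was not tested. Genes with missing values and spots at exactly 0 were not run as alternatives, since no value was missing and at most 20 spots of an array were at 0. No paired analysis was possible because each array already sets a mutant against a wild-type sample and there is 1 group. With genes near the signal floor left out, 3989 genes remained.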

Other observations

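The tests of features printed next to each other, of plate wells and of the CUP1 genes were chosen after the result was seen. Outside the fixed lists 109 genes fell, and several of them were as low as the redox genes. Beyond YLL066C and HSP31, they included YMR090W (-2.67), SSN2 (-2.26), APE1 (-2.09), STB5 (-1.80), SFA1, which encodes a formaldehyde dehydrogenase (-1.64), YPR1 (-1.41), PST2 (-1.40) and ERO1 (-1.10). These were named after their values were seen.

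Of these 109 genes, 33 lay beside another lower gene on the chromosome, against 6.41 on average and at most 13 in the central 95% of 10000 random placements, as shared transcripts or promoters may give. Examples are STB5 beside OYE2, ERO1 beside YML131W, DSF2 (-1.39) beside FLR1, URA8 (-0.69) beside SOD1 and FMP25 (-0.93) beside RPL10. The strands of the neighbours were not compared, so which of these pairs could share a promoter or a transcript was not tested. With every lower gene that had a print neighbour as low left out, 26 genes still had a lower chromosomal neighbour (at most 12 in the central 95% of placements). For these, that argues against signal carried between features adjacent in the inferred print order. Only the previous and the next feature in that order were compared. Chromosomal neighbours mostly stand at fixed offsets in the print order, which could reflect neighbouring plate wells, but 3 genes had a lower partner at these offsets that was not a chromosomal neighbour (at most 13 in the central 95% of placements), and at other offsets 12 genes still had a lower chromosomal neighbour (at most 5). Of the 33, 7 no longer counted, and carried signal stays open for the 4 of these with a print neighbour as low. PTM1, MSN1 and MCH4 had no such print neighbour and dropped out because their lower chromosomal neighbour was left out. Carried signal also stays open for 9 of the 109 with a print neighbour as low or lower (at most 8). Among them were LHS1 (-1.72) and OAC1 (-1.55) in a run that ends at OSI1.

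The higher level of the glycolysis and fermentation list turned sign with median centring, and a dye ratio that changes with brightness is a possible explanation. Against 10000 random lists matched on recovered signal its mean stood at percentile 99.96 after loess and 99.93 after median centring, above their central 95%. PDC1 and FBA1 had a mean log2 signal of 15.8 and 14.9, against 12.1 for PDC6. The brightest of 20 equal groups of spots had a median of 12.7, 12.4 and 11.9 on the 3 arrays. How closely the random lists matched genes as bright as PDC1 and FBA1 was not tested, so brightness stays open. Spots that read the transcripts of related genes stay open: with 1 gene kept from each of the families of related genes, 16 genes remained, 4 of them called higher, and the mean was 0.13 against 0.17 for the full list, at percentile 94.85, inside the central range. Some of these families are less alike than TDH2 and TDH3, and the smaller list has less power. Dye and genotype are the same on all arrays, so a dye effect of these genes' own was not tested.

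CUP1-1, CUP1-2 and RSC30, neighbours on the chromosome, rose together, and more copies of the CUP1 repeat in the mutant strain could give this. YHR054C, within the same repeat, had -0.47 without passing the test, and its difference from the highest of the 6 flanking genes was -0.62. That would go against more copies. It rests on this gene alone, which did not pass, and the spots of the repeat disagree, so more copies stay open. With median centring CUP1-1 (0.17) and CUP1-2 (0.16) did not pass, whereas RSC30 (1.13) did. Stronger copper-responsive transcription cannot be told apart from other causes, because CRS5, the other metallothionein gene, had -0.21 ± 0.15 and neither rose nor fell past 2 standard errors. Without replicate 3 the ratios of CUP1-1 (0.59) and RSC30 (0.73) no longer passed.

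The 3 arrays allow 4 patterns of turned signs, too few for a share under 0.05. The real pattern gave 191 changed genes, the highest of the others 0, and 1 of the 4 patterns gave as many.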
